A study of Homo sapiens with 6 samples.

How the data were processed

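Total RNA of A204 cells was extracted with Trizol, prepared with the Ambion WT Expression Kit and hybridised to Affymetrix GeneChip whole-transcript arrays, per the labels' protocols. There were 3 arrays of cells treated with SAHA for 12 h and 3 of control cells. The controls received DMSO according to the treatment protocol, while another label gives their treatment as none. Groups and replicate numbers were taken from the sample titles and characteristics. The deposited value of each probe set is a signal intensity summarised with RMA, a method of background correction, quantile normalization and probe summarisation, per the submitters' processing notes. The RMA software, its version and the array annotation are not given in the sources used here. The intensity values were deposited on a linear scale, from 6.56 to 20338, whereas RMA gives log2 values, so log2 was taken before every test, as the design fixed before the data were examined had foreseen. RMA brings all arrays to nearly one distribution, so a change of the total RNA per cell would not be seen. Scanner files and detection calls were not used here, so no gene could be called above or below background, and differences of dim genes may be compressed.

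Of 33252 probe sets, 19460 named exactly 1 gene in the platform annotation used, 1754 named several and 12038 named none. Symbols were updated through Entrez identifiers with a RefSeq gene table of GRCh38.p14, which matched 19429 of them, and the remaining 31 kept the older symbol. That table was used for names and for the order of neighbouring genes only, and no coordinates are given because the build of the array annotation is not stated. Each of 18417 genes was represented by its probe set with the highest mean over all 6 arrays. Of 769 genes with several probe sets, 4 (HDLBP, LRRFIP1, PSPH and SSU72) had probe sets called in both directions. No dim gene was left out.

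SAHA was compared with control by a linear model per gene with empirical Bayes moderation (limma 3.58.1 in R 4.3.3, functions lmFit and eBayes, constant prior, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p under 0.05. Every adjusted p given for a gene is limma's, and tests were two-sided except the permutation tests of neighbouring genes, which were one-sided. Levels are means ± SD of 3 arrays on the log2 scale, and changes are SAHA minus control. The 44 gene lists had 799 members as written, of which 706 were measured, and were written before the data were examined. They were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01. As an alternative, the correlation was estimated per list. That alternative also refers the statistic to the 4 residual degrees of freedom, in place of a far larger number set by all genes. A call lost under it therefore need not come from correlation between genes. The fry test, which asks whether a list's genes move on balance one way without reference to other genes, passed for 38 of 44 lists, and its mixed form passed for 44.

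Genes were named by a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, leaving out symbols starting with LOC, RNU, RNA5, SNOR, MIR, RNY, FAM or KIAA and open reading frame symbols. It added the 4 members with the smallest adjusted p of each list that passed, and 2 of other lists described, some of which are left out for length. Of the 10 largest falls, 1 is not reported here. It also added 19 fixed genes, among them all HDAC genes, of which 17 are reported and 2 were not analysed here. Genes named outside the rule are those that differ from their list, RAD50, the histone genes that rose and the gene families of the closing part, chosen after their values were seen.

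The scripts were tested on simulated data with 18417 genes and 6 arrays. For the comparison of SAHA with control, 79.1% of genes changed by 0.5 on the log2 scale were recovered, 100% of those changed by 1 and 100% of those changed by 2, with 6 false calls (3.1% of the calls). A simulated shifted list was called and 0 of 20 unshifted lists were. The simulated genes were drawn independently, so this does not show how often the list test calls lists of correlated genes. Only 67, 67 and 66 simulated genes were changed by these sizes, while 60% of the real genes were called. Recovery, false calls and the list test may differ where so many genes change. The alternatives were a further quantile normalization, centring on the median of the housekeeping list or of all genes, leaving out genes with a mean under 5 or under the median, the mean of a gene's probe sets, all probe sets, eBayes with trend and robust options, an ordinary unmoderated test per gene, array weights, the replicate block, each array left out in turn, the estimated correlation and lists without shared members. Cyclic loess scaling was added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.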

Results

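Gene expression was measured on 6 Affymetrix whole-transcript arrays hybridised with total RNA from A204, an established human cell line from a rhabdoid tumour, a cancer whose typical lesion is loss of the SMARCB1 subunit of the SWI/SNF chromatin remodelling complex. The 3 SAHA arrays came from cells given SAHA (vorinostat), an inhibitor of histone deacetylases (HDACs), for 12 h. The 3 control arrays came from cells given the solvent, per the treatment protocol. The labels print the dose as 10 with an incomplete unit, so the concentration is not stated here. The median RMA signal per array lay between 142 and 149 on the linear scale. Levels of all 33252 probe sets, in log2 units, correlated at 0.9965 to 0.998 (Pearson, across probe sets) between arrays of a group and at 0.9728 to 0.9738 between groups. Genes are not independent replicates. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision.

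The comparison asked which transcripts differed between SAHA-treated and control A204 cells. All measured genes of the DNA replication and mitosis lists were lower after SAHA, many of them by more than 4-fold. Higher were all 9 metallothionein genes, 21 of 28 neuronal genes, 13 of 17 autophagy and lysosome genes and 13 of 14 genes known as induced by HDAC inhibitors. The calls of these 4 higher lists were lost with an estimated correlation (camera adjusted p = 0.119, 0.119, 0.249 and 0.119 in that order). At an adjusted p under 0.05 (limma), 5735 genes were higher and 5314 were lower in SAHA, together 60% of the genes tested. At least 2-fold changes were found for 1075 higher and 998 lower genes, and at least 8-fold changes for 45 higher and 51 lower genes. Rises made up 51.9% of all calls and of the 2-fold calls, but 47.8% and 44.5% when genes under the median level were left out. The 3 SAHA values lay entirely above or below the 3 control values for 12052 genes, 65.4% of those tested against 10% by chance. The median change over all genes was -0.0027 on the log2 scale.

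The largest rise was that of PMEL, which encodes the fibril protein of melanosomes (probe set 7963970). Its log2 level went from 6.35 ± 0.12 in control to 12.28 ± 0.02 in SAHA (SD, n = 3), a 60.9-fold rise. ZCCHC12, a zinc-finger coactivator, rose 55.6-fold, and the orphan receptor gene GPR50 rose 40.1-fold. LIPH, a phospholipase, rose 37.6-fold, and MMP1, the interstitial collagenase, rose 34.4-fold. The chemokine gene CCL20 rose 27.5-fold, ATP1B2, a sodium pump subunit, 25.3-fold, and FABP4, a fatty acid carrier of fat cells, 24.3-fold. ACTBL2 rose 38.3-fold, but its sequence is close to other actin genes and its probes could share their signal. The antisense transcript PKD1L1-AS1 rose 23.7-fold. No background call was made, so the size of a fold against a low control level, such as 4.31 for PKD1L1-AS1, 4.99 for CCL20 or 5.21 for ACTBL2, is not settled. Where the low level is background, the fold of these genes, or of genes that fell to such levels, is a lower bound.

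The largest fall was that of VIT, an extracellular matrix gene, from 11.03 ± 0.12 to 6.81 ± 0.02 (log2, SD, n = 3), 18.6-fold lower. TYMS, which encodes thymidylate synthase and is a classical gene repressed by HDAC inhibitors, was 16.3-fold lower (12.61 ± 0.03 to 8.58 ± 0.07). The other genes of this rank were mostly mitotic genes. SPC25 and NUF2, kinetochore subunits, changed by -3.92 and -3.82 on the log2 scale. The spindle motor KIF15 changed by -3.79, the spindle protein HMMR by -3.57 and the condensin subunit NCAPH by -3.50. CYP27C1, a retinoid desaturase, changed by -3.40. The zinc-finger gene ZNF724 changed by -3.59, with close paralogs that could share its probes.

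**Figure D1:**
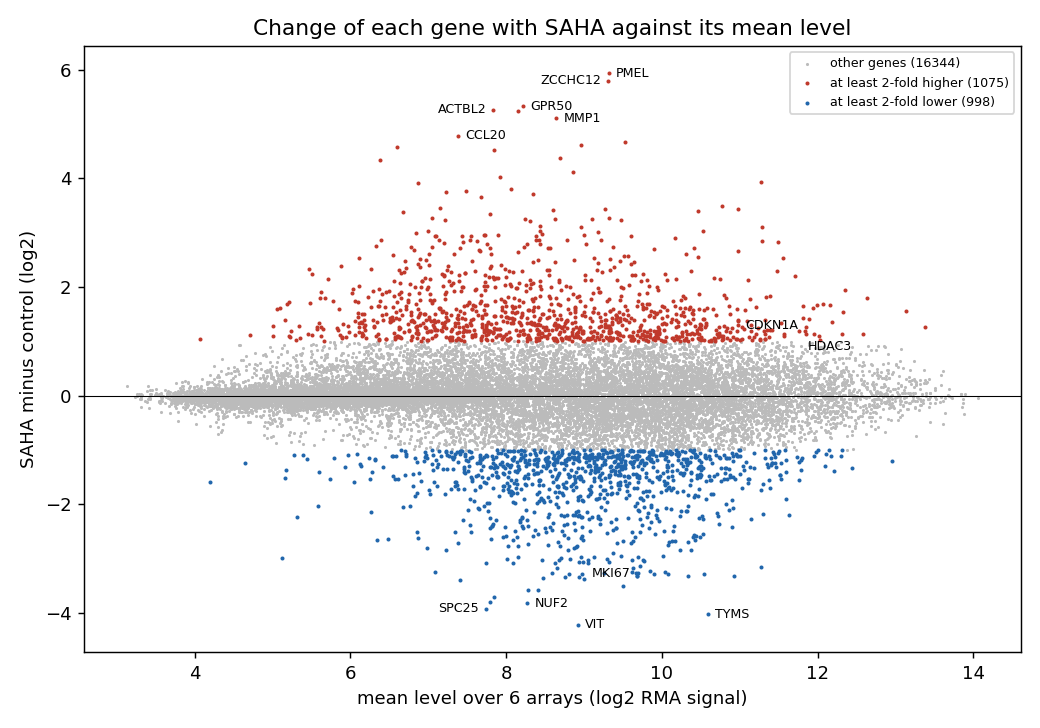
Each point is 1 of 18417 genes, with its mean log2 signal over the 6 arrays on the x axis and the SAHA minus control difference (log2) on the y axis. Red points are the 1075 genes at least 2-fold higher and blue points the 998 at least 2-fold lower at an adjusted p under 0.05; PMEL lies highest at 5.93 and VIT lowest at -4.22.

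The mitosis and DNA replication lists had the largest median changes of the 44 lists. All 34 measured genes of the G2/M and mitosis list fell, each by at least 2-fold, with a median change of -2.92 (camera adjusted p = 8e-21, and adjusted p = 0.0222 with an estimated correlation). MKI67, the proliferation marker Ki-67, fell from 11.32 ± 0.02 to 8.05 ± 0.04, PLK1, a mitotic kinase, changed by -3.16 and KIF20A, a motor needed for cytokinesis, by -3.23. TOP2A, the topoisomerase targeted by anthracyclines, was lower by 2.41 log2 units (12.11 ± 0.03 to 9.69 ± 0.06), as the mean of 3 SAHA against 3 control arrays. All 40 genes of the DNA replication and G1/S list fell, 35 of them at least 2-fold, with a median of -1.82 (adjusted p = 1.84e-20, and adjusted p = 0.0222 with an estimated correlation). Among them RFC3, a clamp loader subunit, changed by -2.55, the replicative helicase subunit MCM7 by -2.27 and the origin recognition gene ORC6 by -2.85.

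Of 23 genes of homologous recombination and checkpoint control, 22 fell and 1, RAD50, was at 0.08 without passing the test. The list median was -1.23 (adjusted p = 3.38e-10, but adjusted p = 0.0613 with an estimated correlation). XRCC2, a recombination repair gene, changed by -3.07, BLM, the Bloom syndrome helicase, by -2.58 and BRCA1 by -2.66. Of 11 G1 cyclins and kinases 9 fell, including the E cyclin CCNE2 (-1.97), the pocket protein RBL1 (-1.90) and CDK4 (-0.61). CCND1, which encodes cyclin D1, fell from 10.79 ± 0.06 to 9.61 ± 0.05. The list passed at adjusted p = 0.00346 and at adjusted p = 0.119 with an estimated correlation it did not. CCND3, the cyclin D3 gene, was the exception that rose, by 0.76, and was named after its value was seen. RB1, the retinoblastoma gene, was at 12.43 ± 0.05 in control and 12.44 ± 0.03 in SAHA, a difference within the replicate spread (adjusted p = 0.848) whose sign turned when the arrays were quantile normalized again (-0.031) or scaled by cyclic loess (-0.0097).

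Replication-dependent histone genes moved both ways: 35 of 46 fell, 8 rose and 3 did not pass the test, with a median of -0.65 (adjusted p = 9.01e-06, but adjusted p = 0.119 with an estimated correlation). With genes under the median level left out, the median of the remaining histone genes was -1.46. The falls included H2AC21 (-3.33), the linker histone H1-5 (-3.29) and H2BC3 (-3.08). Rises of at least 2-fold were those of H4C8 (3.40), H3C10 (2.12), H2BC21 (1.64), H2AC11 (1.63) and H2BC5 (1.18), named after their values were seen. Histone genes are near-identical copies, so each value could include signal from other copies. Of 8 replacement histone genes 3 rose and 4 fell, and the list did not pass (adjusted p = 0.341). MACROH2A2, a macroH2A variant of silent chromatin, went from 10.61 ± 0.05 to 7.27 ± 0.06.

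Every measured HDAC gene passed the test, 8 higher and 3 lower, with none changed 2-fold, and the list as a whole did not stand apart from other genes (adjusted p = 0.351). HDAC3, the catalytic subunit of the NCoR and SMRT corepressor complexes, was the most raised, from 11.34 ± 0.07 to 12.24 ± 0.03. HDAC1 rose by 0.39, HDAC4 and HDAC5 each by 0.30, HDAC6 by 0.23, HDAC9 by 0.59 and HDAC11 by 0.51. HDAC2 changed by -0.27, HDAC7 by -0.82 and HDAC8 by -0.73. HDAC10 rose by 0.23 at adjusted p = 0.0464. Its call ended without control replicate 1 (0.14, adjusted p = 0.119), without control replicate 2 (adjusted p = 0.0804), without SAHA replicate 2 (adjusted p = 0.123) and without SAHA replicate 3 (adjusted p = 0.127). It also ended with all probe sets tested (adjusted p = 0.0864) and with the ordinary unmoderated test per gene (adjusted p = 0.142), and the adjusted p ran from 0.0131 to 0.142 over 18 alternatives. Of 11 histone acetyltransferase genes 4 rose and 7 fell (adjusted p = 0.313), with KAT2A, the GCN5 enzyme, lowest at -1.16.

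Genes known from textbooks as induced by HDAC inhibitors were raised, 13 of 14, with a median of 1.24 (adjusted p = 5.64e-05, but adjusted p = 0.119 with an estimated correlation). DHRS2, a short-chain dehydrogenase, rose 16.2-fold, from 5.91 ± 0.33 to 9.93 ± 0.08. TXNIP, the thioredoxin inhibitor, rose by 1.94 and the chaperone clusterin, CLU, by 1.66. CDKN1A, which encodes the cell-cycle inhibitor p21, rose 2.46-fold, from 10.33 ± 0.07 to 11.63 ± 0.03. The exception was GSN, the actin-severing protein gelsolin, which fell by 0.35 and was named after its value was seen. Of 11 genes known as repressed, 9 fell with a list median of -0.97 (adjusted p = 0.000751, but adjusted p = 0.119 with an estimated correlation), among them RRM2, a ribonucleotide reductase subunit, at -2.24 and CTPS1, a CTP synthase, at -0.98. Most genes of this list are also on other lists, such as TYMS and RRM2 on the DNA replication list. Too few remained to test it without shared members, so its fall is not separate from that of those lists. MYC, the proto-oncogene, rose by 0.23, from 11.74 ± 0.04 to 11.97 ± 0.02. Among 7 CDK inhibitor genes 4 rose and 3 fell (adjusted p = 0.958).

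**Figure D2:**
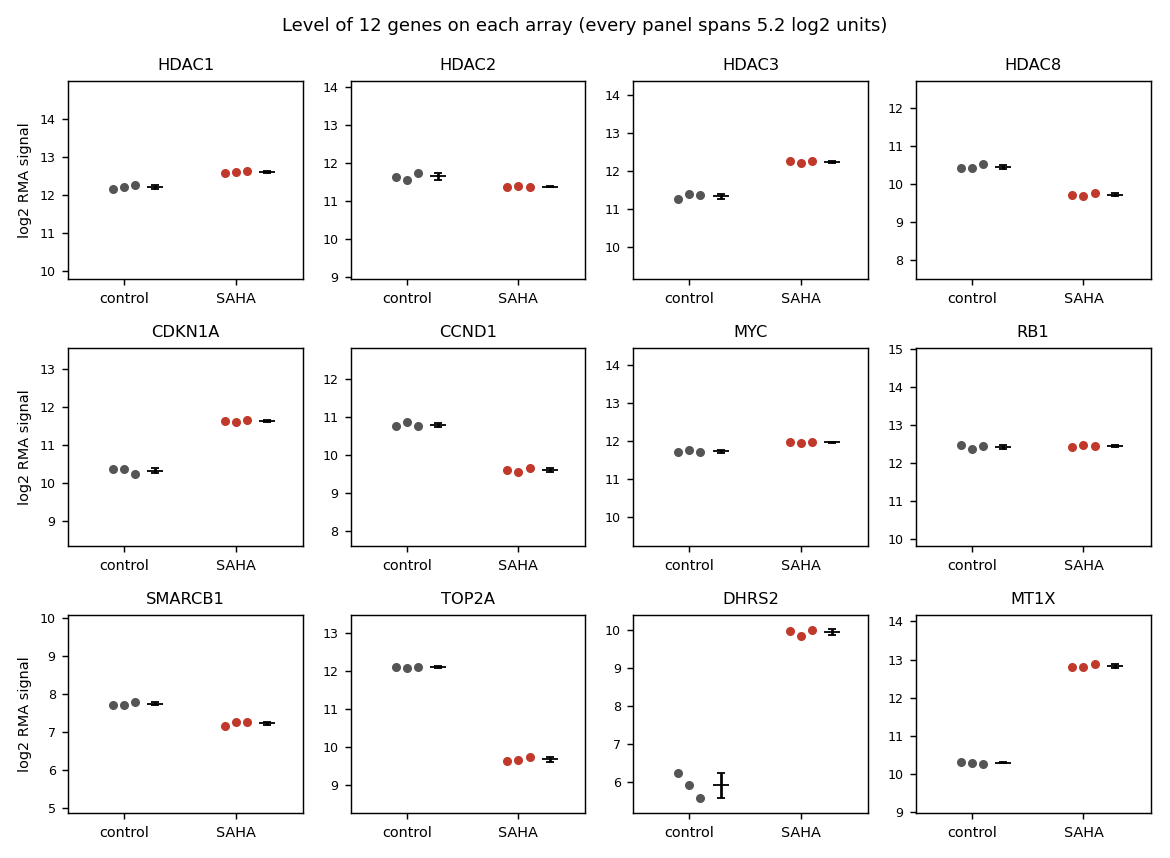
Log2 RMA signal (y axis) of 12 genes on each of the 3 control and 3 SAHA arrays (x axis), with the mean and SD at the right of each group; every panel spans 5.2 log2 units. CDKN1A lay between 10.25 and 10.37 in control and between 11.60 and 11.66 in SAHA, while the RB1 values of both groups overlapped.

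All 9 metallothionein genes, whose products bind zinc and copper, rose, with a median of 1.24 (adjusted p = 0.000116, but adjusted p = 0.119 with an estimated correlation). MT1F rose 7.21-fold, MT1X 5.81-fold and MT2A 2.39-fold, although these genes are close copies whose probes could share signal. Of 28 neuronal genes 21 rose, none fell and 7 did not pass, with a median of 0.54 (adjusted p = 2.79e-06, but adjusted p = 0.119 with an estimated correlation). With genes under the median level left out, the median of the remaining neuronal genes was 1.45. That level is the mean over all 6 arrays, so a gene dim in control can stay in through its rise in SAHA. The filter itself may therefore have raised this median. ELAVL3, a neuronal RNA-binding protein gene, rose from 7.52 ± 0.11 to 10.48 ± 0.06, the synaptic vesicle gene RAB3A by 2.14, MAPT, which encodes tau, by 2.06 and the vesicle calcium sensor SYT1 by 1.51. Of 17 autophagy and lysosome genes 13 rose, 1 fell and 3 did not pass (median 0.40, adjusted p = 0.000327, but adjusted p = 0.249 with an estimated correlation). The lysosomal enzymes NEU1 and CTSB rose by 1.61 and 1.27, the lysosomal channel MCOLN1 by 1.25 and the autophagy receptor SQSTM1 by 1.13. The gene that fell was ATG7, which encodes an enzyme of autophagosome formation, at -0.13, named after its value was seen.

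Growth and biosynthesis lists were lower by smaller amounts. Of 27 ribosome biogenesis genes 16 fell and 4 rose (median -0.39, adjusted p = 0.00306, but adjusted p = 0.263 with an estimated correlation), including UTP20 (-1.69) of the small-subunit processome, the ribosome assembly gene MRTO4 (-1.29) and DKC1 (-1.03), the dyskerin gene. Of 20 other MYC targets 14 fell and 3 rose (median -0.38, adjusted p = 0.00644, but adjusted p = 0.119 with an estimated correlation). PAICS, a purine synthesis enzyme, changed by -0.68 and the folate enzyme MTHFD1 by -0.71. Without genes shared with other lists, such as TYMS, this call ended (median -0.17, adjusted p = 0.328).

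Of 10 antigen presentation genes 7 fell and 1 rose (median -0.63, adjusted p = 0.0113, but adjusted p = 0.333 with an estimated correlation and 0.111 when genes under the median level were left out). The peptide transporter TAP1 changed by -1.32, the loading chaperone TAPBP by -1.22 and the trimming peptidase ERAP1 by -1.85. B2M, the class I light chain, was the gene that rose, by 0.70, and was named after its value was seen. Of 21 SWI/SNF subunit genes 14 fell and 5 rose (median -0.42, adjusted p = 0.0279, but adjusted p = 0.394 with an estimated correlation, 0.0686 after a further quantile normalization and 0.0576 without control replicate 3). The falls included ARID2 (-1.31), ARID1B (-1.23) and ARID1A (-0.66), while the ATPase gene SMARCA2 rose from 5.92 ± 0.13 to 7.51 ± 0.08. ACTL6B and DPF1, subunits of the neuronal form of the complex, rose by 1.94 and 1.04 and were named after their values were seen. SMARCB1 went from 7.74 ± 0.04 to 7.22 ± 0.05 (adjusted p = 2.28e-05). Loss of this subunit is typical of rhabdoid tumours and no background call was made. Whether its signal comes from an intact transcript is therefore not settled. Of 14 retinoid pathway genes 8 fell and 2 rose (median -0.26, adjusted p = 0.0401). That call did not hold with an estimated correlation (adjusted p = 0.348), after a further quantile normalization (0.0707) or with the replicate block (0.0564). It also ended without genes under the median level (0.0982), without control replicate 3 (0.0555) and without SAHA replicate 3 (0.0588). The median of the list was -0.15 over all probe sets, where the call held. DHRS3, a retinal reductase, changed by -2.28 and the retinol transporter STRA6 by -1.33, whereas ALDH1A1, which makes retinoic acid, rose by 2.59.

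**Figure D3:**
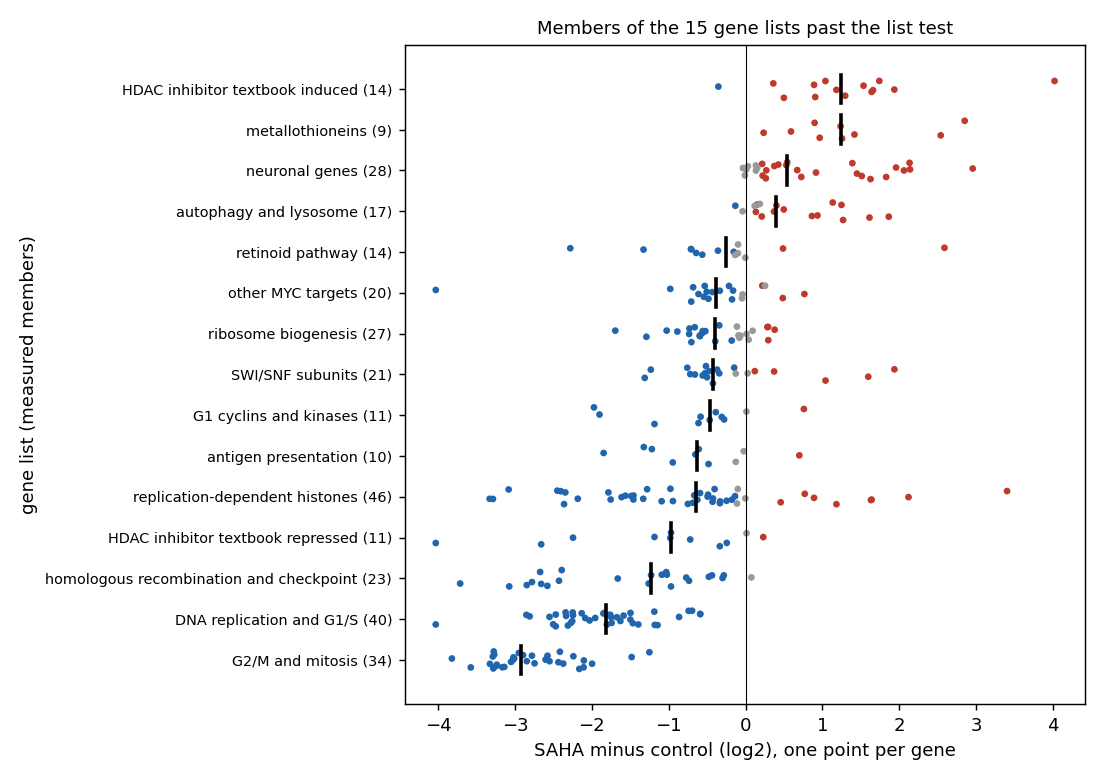
SAHA minus control difference (log2, x axis) of each measured member of the 15 gene lists with an adjusted p under 0.05 (y axis, number of members in brackets); red points rose, blue points fell, grey points did not pass and black bars are list medians. All 34 G2/M and mitosis genes lie below 0, with a median of -2.92, and all 9 metallothionein genes lie above 0.

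The remaining lists did not pass in the main test, although single members changed. Of 20 p53 target genes 8 rose and 8 fell (adjusted p = 0.958), with the death receptor gene FAS at -1.90. The unfolded protein response list had 10 genes higher and 3 lower (adjusted p = 0.079, but 0.0307 over all probe sets and 0.0398 with the ordinary unmoderated test per gene), with the stress factor ATF3 at 1.36 and XBP1, a regulator of that response, at -1.16. Of 18 mesenchymal genes 9 rose and 6 fell (adjusted p = 0.629), fibronectin, FN1, by 3.25 and the transcription factor SNAI1 by 2.09. Among 14 smooth muscle and SRF or YAP targets 5 rose and 8 fell (adjusted p = 0.913), with ANKRD1 at 3.49 and TAGLN, transgelin, at -1.44. Of 20 receptor tyrosine kinase genes 13 rose and 6 fell (adjusted p = 0.199, but 0.0359 over all probe sets), with FGFR4 at 2.31. Of 18 interferon-stimulated genes 8 rose and 6 fell (adjusted p = 0.837), with BST2, tetherin, at 2.87. Of 22 skeletal muscle genes 6 rose, 3 fell and 13 did not pass (adjusted p = 0.958), with desmin, DES, at 0.76. Among markers of other cell types, 8 of 10 blood cell genes did not pass (adjusted p = 0.958), while CD14, the lipopolysaccharide coreceptor, rose from 8.94 ± 0.08 to 10.94 ± 0.04. Of 9 endothelial genes 5 did not pass and the list did not either (adjusted p = 0.913). CDH5, VE-cadherin, was at 12.73 ± 0.03 in control and 10.54 ± 0.03 in SAHA. Of 10 housekeeping genes 3 rose, 3 fell and 4 did not pass (adjusted p = 0.958).

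Genes were tested with limma and lists with camera, both with Benjamini-Hochberg adjustment, and 15 of 44 lists passed, 4 of them higher and 11 lower in SAHA. Only the G2/M and mitosis list and the DNA replication list also passed with an estimated correlation between genes. That setting also uses fewer degrees of freedom, so it does not isolate the effect of correlation. Counts adjusted over the list alone equalled those given except in 5 lists. They were 23 higher for the neuronal genes, 5 higher and 0 lower for skeletal muscle, 3 higher and 8 lower for heat shock proteins, 2 higher and 1 lower for cancer-testis antigens, and 0 higher and 1 lower for endothelial markers. Median, mean and test differed in sign for 10 lists, none of which passed: CDK inhibitors, p53 targets, death receptors, pluripotency, skeletal muscle, smooth muscle targets, Hedgehog pathway, cancer-testis antigens, blood cell markers and housekeeping genes.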

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

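Outside the genes tested, 12038 probe sets named no gene in the annotation used. Of these, 110 were at least 2-fold higher in SAHA than in control and 219 at least 2-fold lower (limma, adjusted p under 0.05), a signal in probe sets outside the genes of the main comparison, used otherwise only in the alternative that tests all probe sets. Likewise, 81 of the 1754 probe sets that name several genes were at least 2-fold higher and 70 at least 2-fold lower. Both kinds of probe set changed less often than the 18417 genes tested, of which 1075 were at least 2-fold higher and 998 at least 2-fold lower. No explanation of the changes in these probe sets was tested.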

How the results depend on the processing

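Across the alternatives, 89 of 92 counts of calls stayed within 1.5 times the count given. With genes under the median level left out, which removes 9208 of 18417 genes, 3660 genes were higher and 611 at least 2-fold higher, and falls outnumbered rises, as they did among all calls after a further quantile normalization (48.6% higher) and over all probe sets (47.8% higher, and 49.3% of 2-fold calls). With an estimated correlation between genes, which also brings fewer degrees of freedom, 2 lists passed in place of 15. For named genes, 2491 values kept direction and call, 13 lost the call and 4 turned direction. For lists, the numbers were 826, 22 and 23, and 3 gained a call, the unfolded protein response list under 2 alternatives and the receptor tyrosine kinases under 1, over all probe sets. The lost gene calls were 6 of HDAC10, 6 of ERG (adjusted p from 0.0177 to 0.0955 over 16 alternatives) and 1 of CD79A (0.0511 with the ordinary unmoderated test). Those of ERG came with eBayes trend and robust options (0.0955), with the replicate block (0.065), without control replicate 2 (0.0683) and without SAHA replicate 1 (0.0658), 2 (0.0676) or 3 (0.0877). Every turn of direction was in a gene or list that had not passed, and the cause was not tested. Under a further quantile normalization RB1 was at -0.031, and list medians were -0.091 for skeletal muscle, -0.0096 for cholesterol synthesis and -0.081 for blood cell markers. Under cyclic loess, chosen after seeing the data, RB1 was at -0.0097, skeletal muscle at -0.071 and blood cell markers at -0.036. Centring on housekeeping genes turned the CDK inhibitors (median 0.16). Leaving out genes under the median level turned pro-apoptotic genes (-0.026), death receptors (-0.083), Polycomb genes (0.050), TGF-beta genes (-0.15) and housekeeping genes (0.037). The housekeeping list, with the same median of 0.037, also turned with all probe sets and with the ordinary unmoderated test, as did death receptors with the latter (-0.0014). Without shared members CDK inhibitors were at -0.30, anti-apoptotic genes at 0.087, death receptors at -0.083 and pluripotency genes at 0.071. With each array left out in turn, RB1 ran from -0.018 to 0.032, blood cell markers from -0.059 to 0.015, pluripotency genes from 0.020 to 0.060 and p53 targets from -0.025 to 0.020. These list medians can keep their sign where the test's direction turned. Arrays with the same number did not deviate together (correlations of -0.03, -0.167 and -0.004), so the numbers were not taken to pair them. With the replicate block, 5520 genes were higher and 5081 lower, the retinoid list was at adjusted p = 0.0564, and blood cell markers turned at a median of -0.024. The adjusted p over 20 alternatives ran from 0.0307 to 0.509 for the unfolded protein response, 0.0359 to 0.712 for receptor tyrosine kinases, 0.00584 to 0.394 for the SWI/SNF list, 0.0196 to 0.348 for the retinoid list, 0.00196 to 0.328 for other MYC targets and 3.68e-06 to 0.333 for antigen presentation. The median of all genes lay between -0.031 and 0.021 under the 4 scalings. Without detection calls, the signal over background that limits dim genes is unknown.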

Other observations

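The gene families of this paragraph and the next were chosen by symbol after the data were seen, as were the tests of the histone pattern below. All 10 measured genes of the MHC class II family rose after SAHA, 5 of them at least 2-fold, the pseudogene HLA-DPB2 included. Apart from that pseudogene, they encode chains that present extracellular peptides to helper T cells or act in their loading. The median of all 10 was 0.998 (camera adjusted p over 19 families = 0.000345, but adjusted p = 0.086 with an estimated correlation). HLA-DMB, a peptide exchange factor, rose 8.63-fold from 7.41 ± 0.13 to 10.52 ± 0.15 (log2, SD, n = 3), HLA-DPA1 7.80-fold and HLA-DPB1 6.91-fold. CIITA, the master regulator of class II genes, was at 6.83 ± 0.08 in control and 6.72 ± 0.06 in SAHA (limma adjusted p = 0.131). Class II genes are close paralogs and their probes could share signal. Of 27 HOX genes, which set body-axis identity, 12 rose and none fell (adjusted p = 0.04, but adjusted p = 0.179 with an estimated correlation), and HOXC10 rose by 1.38.

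Zinc-finger ZNF genes, many of them transcriptional repressors and close paralogs, were lower more often than higher: 237 of 494 fell and 95 rose, with a median of -0.14 (adjusted p = 0.000782, but adjusted p = 0.0846 with an estimated correlation). ZNF730 changed by -1.97 and ZNF43 by -1.94. All 13 condensin and SMC genes, which shape and hold chromosomes, fell (adjusted p = 1.03e-06, but adjusted p = 0.086 with an estimated correlation), with NCAPG at -3.28 and SMC4 at -2.61. Of 74 mitochondrial ribosomal protein genes 39 fell and 15 rose (adjusted p = 0.0125, but adjusted p = 0.346 with an estimated correlation). Of 66 cytosolic ribosomal protein genes 24 fell and 4 rose, with a median of -0.07 (adjusted p = 0.04, but adjusted p = 0.391 with an estimated correlation). Taken by symbol, this family includes paralogs such as RPL22L1 (-1.64) and RPL3L (1.34), its only members changed at least 2-fold. It was not tested without such paralogs. These 6 of the 19 families passed, and the lowest adjusted p with an estimated correlation was 0.0846. Medians of the 6 families kept their sign under the 4 scalings. Single genes outside the named lists included KRT20, an intestinal keratin, raised 22.9-fold, SERPINE2, a protease inhibitor, raised 17.3-fold and the neutrophil chemokine CXCL8, raised 6.35-fold. SERPINH1, the collagen chaperone HSP47, was at 12.28 ± 0.06 in control and 10.00 ± 0.04 in SAHA.

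The number of calls was set against other splits of the 6 arrays into 3 and 3. The real split gave 11049 genes and 1 of the 10 splits, the real one, gave as many, while the highest other split gave 0 with limma and at most 175 genes at an unadjusted p under 0.05. With 10 splits the share cannot fall below 0.1, which is too few splits for a share under 0.05. Each of the other splits also mixes SAHA and control arrays in both groups. The difference between SAHA and control then widens the spread within groups and holds calls down. Few calls in those splits therefore give no measure of chance.

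At least 2-fold changes were mostly rises among dim genes and more often falls among bright ones. With genes divided by mean level into 3 equal bins, in the dimmest bin 185 were higher and 52 lower (78.1% higher), in the brightest 351 and 438 (44.5% higher), a difference of 33.6 percentage points. The difference kept at least 0.725 of its size under 4 scalings. Centring moves a whole array alike and a further quantile normalization repeats a step of RMA, so these were weak tests. Cyclic loess, which adjusts by level, still gave 76.8% higher in the dimmest and 47.1% in the brightest bin. This argues against array scaling as the whole cause, although cyclic loess was chosen after seeing the data. Without detection calls, the limit that background sets on falls of dim genes is unknown. The biological difference that the design names, the response to SAHA, stays open and was not tested separately.

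Genes at least 2-fold higher lay next to each other along chromosomes in 91 pairs, against a median of 66 in 10000 permutations within 20 bins of level. Neighbours that respond together could give this, and so could related genes that sit side by side. Without pairs whose symbols share their first 3 letters, 74 pairs remained against a permuted median of 60 (one-sided permutation p = 0.040). The upper bound was 75, a percentile of the permutations chosen before the result was seen. By the rule written before, the count met the outcome for related genes and not that for neighbours. However, it lies only 1 pair under that bound, within the spread of the permutations, so these explanations cannot be told apart. For genes at least 2-fold lower, also without pairs whose symbols share their first 3 letters, 74 pairs stood over a permuted median of 55. The upper bound was 69 (one-sided permutation p = 0.005). Histone genes of different families that fell, such as H3C2 and H2BC3, differ in these letters. Related genes can therefore remain among these pairs, and the count does not separate the explanations either.

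Replication-dependent histone genes moved both ways, and 3 explanations were weighed. Fewer cells in S phase would lower these genes and could underlie the 35 that fell, but 5 genes at least 2-fold higher argue against it as the whole cause. Cross-hybridisation between near-identical copies stays open: 4 of the histone families held 2-fold calls in both directions, but in 3 of them only 1 gene was 2-fold higher, and probes that share part of their signal need not make a family move alike. A candidate explanation for the rises is polyadenylated histone transcripts, since 4 of 7 genes listed as giving them rose against 4 of 39 others (Fisher's exact test, two-sided p = 0.012). However, 3 of the 7 were also on the list of known induced genes, and without them 1 of 4 rose (exact p = 0.4), so this stays open.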
